A study of Homo sapiens with 5 samples.

How the data were processed

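The series examined the lysine demethylase LSD1, encoded by KDM1A, in androgen signalling in the human prostate cancer cell lines LNCaP and VCaP. It held 5 samples, each the only one of its group. There were 3 chromatin immunoprecipitation (ChIP-seq) peak lists, for LSD1 in LNCaP, LSD1 in VCaP and histone H3 phosphorylated at threonine 6 (H3T6ph) in LNCaP. There were 2 RNA-seq libraries from LNCaP, transfected with a control siRNA or an siRNA against LSD1. Per the labels' protocols, cells were kept for 3 days in medium with charcoal-stripped serum before a hormone stimulus, which the labels do not name. ChIP libraries were made with the ThruPLEX-FD kit and RNA libraries with the TruSeq RNA kit v2, per the labels' protocols.

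The submitters' processing notes name Bowtie2 2.0.0, TopHat2 2.0.4, MACS2 without a version, Cuffdiff 2.0.1 and the genome build hg19. Expression was deposited as FPKM, 1 value per RefSeq accession and library, in a table with the column layout of Cuffdiff, per the file headers. The same table gives the authors' p-value and q-value for each accession, and every accession the authors called changed has a q under 0.05. The log2 fold change column of that table was not used, because it holds placeholder values where a library is at 0. Each peak list was deposited with a score per peak by the authors. Its scale is not stated in the file, and scores were used only to rank peaks within a list. Peaks were called per sample, with 1 list for each. The control track, the treatment of duplicate reads, the library scaling and the annotation version are not given in the sources used here.

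Of 40253 accessions, 38934 (96.7%) were matched to a gene symbol through the RefSeq gene table of assembly GRCh38.p14, which was used for names, gene types and lengths only. The 1319 accessions without a match were not analysed by gene. FPKM of the accessions of a symbol were summed, and 42 genes with an accession that the authors' program marked as failed were left out. A gene entered the comparison at 1 FPKM or more in either library, which left 12916 genes, 11753 of them protein-coding. Fold changes are on the log2(FPKM + 1) scale, LSD1 siRNA over control siRNA, and understate the change of low genes. With 1 library per group there is no spread between replicates, no difference has a replicate check, and no p-value was computed across genes. Genes were called higher or lower by a fixed size, a 2-fold change on that scale. Table positions are intervals that can span overlapping transcripts and carry no strand, so distances were taken from the gene interval. TruSeq v2 does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart.

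The table gives no read totals. Low values rise in steps of 1 read, and the most frequent ratio of low values put the worth of 1 read 1.29 times higher in the LSD1 siRNA library, a depth of 77.3% of the control library. A line through the values of single-read olfactory receptor genes without introns gave an estimated 33.0 M and 25.5 M fragments for the control and LSD1 siRNA libraries, with 204 bases taken off each length. Under this estimate 41 of 41 and 44 of 44 such genes came out at whole fragments within 0.05. A transcript of 2 kb at 1 FPKM would then rest on about 59.3 and 45.8 fragments.

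Gene lists were scored by their median log2 fold change and its percentile among 10000 random lists of protein-coding genes, matched on mean expression in 20 bins. This describes these libraries and is not a test of the conditions. The 25 lists were fixed before the data were examined, as were the 2-fold rule, the 20 kb distance and the alternatives called planned. Chosen after seeing the data were the sum over accessions, the removal of failed accessions, the protein-coding background, the split of genes at 300 bases, the separate count of protein-coding genes, the gene families, the shared-peak gene sets and the depth estimate. The rule for named genes took KDM1A, the 10 largest increases and 10 largest decreases among called genes at 5 FPKM or more, the 2 to 4 members of each list with the largest absolute change, the 3 highest-scoring peaks of each list and the peaks nearest a fixed set of genes that included KLK3, KLK2, TMPRSS2, FKBP5 and KDM1A. Some results that this rule and the fixed lists take in are not reported here. Genes on chromosome Y were not named.

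Peaks were compared with bedtools 2.31.1, with at least 1 shared base. Shares carry 95% Wilson intervals, which cover counting error only. Each share stands beside 100 random placements of the other list within the same chromosomes, up to the largest coordinate seen in the files. These placements ignore unmappable sequence and therefore give somewhat low values. As an added comparison each peak of the other list was moved by 50 to 500 kb at random. A gene had a peak nearby when a peak lay within 20 kb of its interval. Shares of genes with a peak were set against 10000 random gene sets matched on mean expression, and again on mean expression and interval length (5 bins). Coordinates are 1-based in hg19. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

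The calculations were tested on simulated data. Among 12514 simulated genes for the comparison of the siRNA libraries, the 2-fold rule recovered 0% of genes changed 1.5-fold, 78% of those changed 2.5-fold, 96% of those changed 4-fold and 100% of those changed 8-fold, and called 0% of unchanged genes. The simulated noise was small and of fixed size, without counting error, and genes under 300 bases were left out. These percentages therefore do not give the rate of false calls in the real libraries, least of all for short genes. Of 100 unchanged lists 4 fell outside the middle 95% of random lists, and 20 of 20 shifted lists fell below percentile 2.5. Fold changes were permuted across genes for these lists, which removes any shared variation of list members. The 4 of 100 therefore checks the calculation only and does not give the rate for real lists, whose members can vary together. A planted overlap of 30% between simulated peak lists was returned as 30%. The alternatives tried were a pseudocount of 0.1 FPKM, no filter, a filter of 5 FPKM, a 1.5-fold threshold, centring, the authors' own calls, other definitions of overlap, score cuts, distances of 5 and 50 kb, and sets matched on length.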

Results

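The data covered 5 samples of the prostate cancer cell lines LNCaP and VCaP. The design text of the series asks about the role of LSD1 in androgen signalling. LSD1 is a histone demethylase that works in the CoREST and NuRD complexes and has been described as both a repressor and a coactivator. H3T6ph is a mark placed by protein kinase C that is known to alter the substrate preference of LSD1. Each group held 1 sample, so no value below has an error between replicates. The RNA table listed 12916 genes at 1 FPKM or more in either library. The LSD1 siRNA library had an estimated depth of 77.3% of the control library. Depth is unknown for the ChIP samples, for which peak lists were used. LSD1 had 11673 peaks in LNCaP and 9854 in VCaP, and H3T6ph had 4460 peaks in LNCaP.

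The first comparison asked which transcripts differed in LNCaP after LSD1 siRNA. KDM1A, the targeted gene (chromosome 1, 23345941 to 23410184, hg19), was at 37.0 FPKM with control siRNA and 6.87 FPKM with LSD1 siRNA. That is 18.6% of control and a log2 fold change of -2.27, and the authors' deposited table lists its q as 0.

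By the 2-fold rule 109 genes were higher and 146 lower after LSD1 siRNA. Genes under 300 bases, mostly microRNA and small nucleolar RNA genes, made up 224 of these 255. The 10 largest increases by the rule were all listed at 0 FPKM in the control library. They were MIR4701, SNORD42A, SNORD18B, SNORD37, MIR302B, SNORD42B, SNORD82, MIR4639, MIR31 and MIR3689C, at 135 to 379.5 FPKM after LSD1 siRNA. The 10 largest decreases were all listed at 0 FPKM after LSD1 siRNA. They were SNORD44, MIR4750, MIR3685, SNORD102, MIR3650, SNORD75, MIR3677, MIR200C, SNORD34 and SNORD98, at 349 to 2005 FPKM in the control library. None of these 20 was called in the authors' deposited table, and MIR3650, SNORD75 and MIR3677 shared the same control value of 478 FPKM. The depth estimate takes 204 bases off each length, so values of genes this short are not a reliable measure of the named RNAs.

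Among protein-coding genes 13 rose and 15 fell past 2-fold, counting KDM1A. The authors' deposited table called an accession of 17 of these 28. They are named here after their values were seen, because the 10 largest changes in each direction were short RNAs. The total counts were 247 and 311 at 1.5-fold, and the authors' deposited table called 63 accessions higher and 79 lower. The rise was largest in level for DIO3, the deiodinase that inactivates thyroid hormone, from 213 to 567 FPKM (log2 1.41). MAN1A1, a Golgi mannosidase, rose from 3.23 to 9.79 FPKM (log2 1.35). CLU, the secreted chaperone clusterin, rose from 18.2 to 47.0 FPKM (log2 1.32). The small heat shock protein gene CRYAB (log2 1.21), the metalloprotease gene MMP7 (1.17), the interleukin-1 receptor antagonist gene IL1RN (1.11), the desmosomal gene PERP (1.04) and OGFR (1.02) were also called in both ways. The largest fall after KDM1A was in STEAP4, a metalloreductase gene, from 9.89 to 2.52 FPKM (log2 -1.63). NPPC, which encodes C-type natriuretic peptide, fell from 7.13 to 1.81 FPKM (log2 -1.53). DCTPP1, a nucleotide pyrophosphatase gene, fell from 62.9 to 22.9 FPKM (log2 -1.42). ADAM7 (log2 -1.16), SPAG16 (-1.11), ADIPOR1 (-1.11) and B4GALT5 (-1.06) also fell and were called by the authors, as was OTULINL, from 18.7 to 8.82 FPKM. The 2-fold rule alone called APOL3, KRTAP19-1, PEDS1-UBE2V1, BLOC1S5 and RPL21 higher. It alone called IFI27, PHOSPHO2-KLHL23, FYTTD1, GGT1, CCAR2 and MICOS10-NBL1 lower. RPL21 is uncertain, because it has many near-identical pseudogene copies and is listed at the same interval as SNORD102. Readthrough genes such as PEDS1-UBE2V1 share exons with their neighbours and are uncertain for the same reason. Of protein-coding genes 97.8% lay within 1.5-fold, with a median log2 fold change of -0.01 and an SD across genes of 0.23.

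Genes that androgen is known to induce in prostate cells were lower as a group after LSD1 siRNA. The 2 RNA libraries do not differ in hormone treatment, so a weaker response to androgen cannot be told apart from a lower basal level. Of 47 measured members of the list, 42 had a lower value and 5 a higher one, with a median log2 fold change of -0.38. This lay below all of the 10000 matched random lists, whose medians ran from -0.14 to 0.12. STEAP4 and ADAM7 fell past 2-fold. The next largest difference was in CENPN, a kinetochore gene, at 157 and 89.2 FPKM (log2 -0.81). In all, 12 members were lower by at least 1.5-fold, among them FKBP5 (log2 -0.72), an androgen-induced co-chaperone gene. KLK3, which encodes prostate-specific antigen, was at 2474 and 1941 FPKM (log2 -0.35). KLK2 was at 339 and 254 FPKM (log2 -0.41), and TMPRSS2 at 357 and 279 FPKM (log2 -0.36). Of the 47 members only STEAP4, ADAM7 and CENPN had an accession called in the authors' deposited table. FKBP5, KLK3, KLK2 and TMPRSS2 had none.

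**Figure D1:**
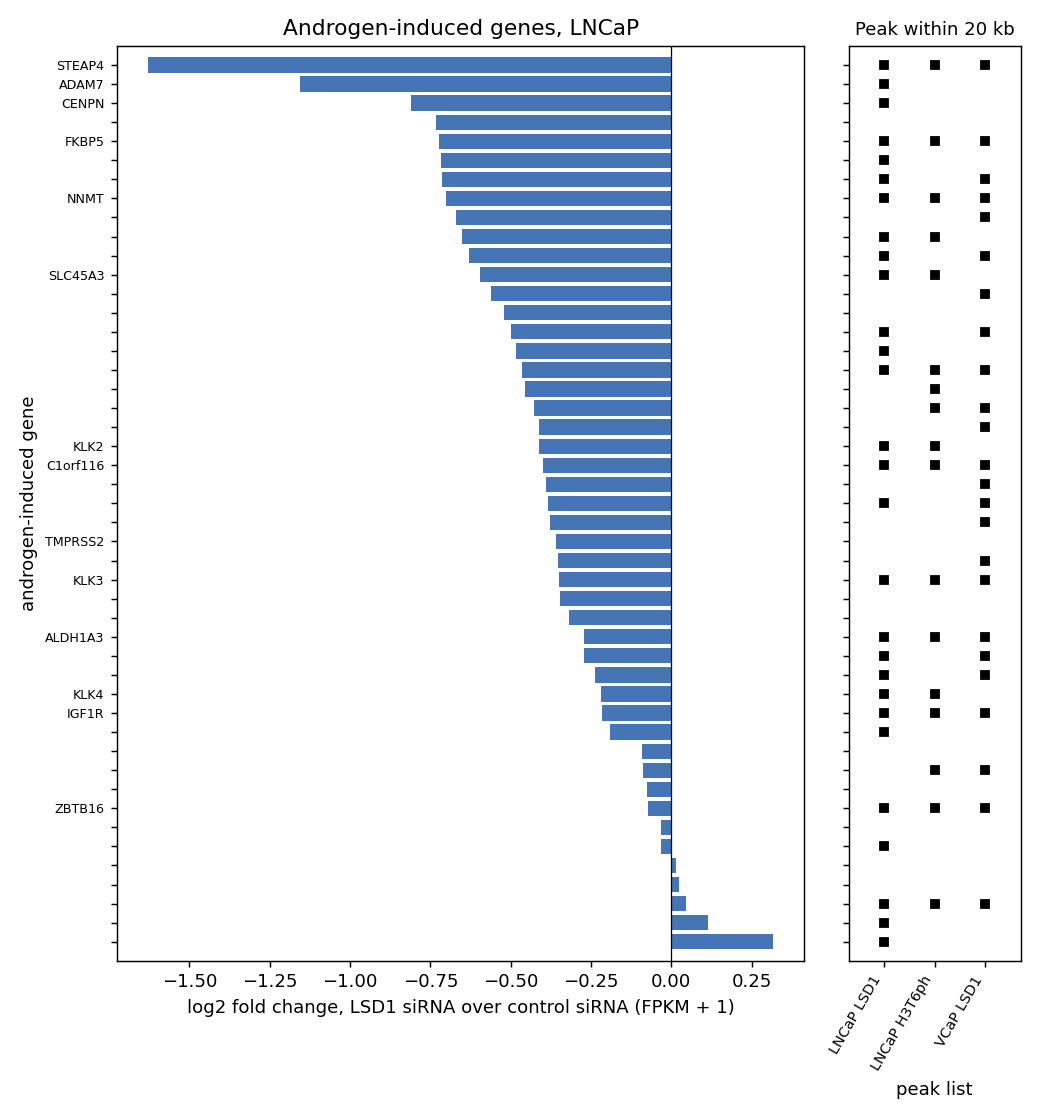
Each bar is the log2 fold change of 1 androgen-induced gene in LNCaP, LSD1 siRNA over control siRNA on the FPKM + 1 scale, with 1 library each, and squares mark genes with a peak of the named list within 20 kb, with names for genes described in the text. Of the 47 genes 42 lie below 0, with STEAP4 (-1.63) and ADAM7 (-1.16) lowest.

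Genes reported to be lowered by androgen did not stand apart from random lists. Their median log2 fold change was 0.07 over 19 measured genes, at percentile 94.8. CAMK2N1 had a log2 fold change of 0.51, while MYC was at -0.55 and ACKR3 at -0.50.

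DNA replication genes were lower as a group, in 33 of 34 members, with a median of -0.23 that lay below all random lists. None passed 1.5-fold. CDC6, a replication licensing factor gene, was at -0.57, and the helicase subunit genes MCM5 and MCM6 were at -0.56 and -0.44. Mitosis genes, with a median of -0.04 over 26 members, lay at percentile 26.8, with CCNB1 at -0.31 and NUSAP1 at -0.22. Cholesterol synthesis genes had a median of -0.13 at percentile 1.27, with HMGCS1 at -0.55 and FDFT1 at -0.54. Fatty acid synthesis genes had a median of -0.13 at percentile 2.73, with ELOVL7 at -0.59 and ACACA at -0.55.

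Immediate early genes were higher as a group, with 14 of 16 members above 0 and a median of 0.38 that lay above all random lists. EGR1 was at 0.65, IER2 at 0.61 and CCN1 at 0.56, while MYC was at -0.55. The interferon response list had a median of 0.14 over 32 members, above all random lists, although its most changed member, IFI27, fell (log2 -1.41). RSAD2 was at 0.53. Hypoxia genes, 18 of 19 of them above 0, had a median of 0.16 at percentile 99.9, with CA9 at 0.59 and ADM at 0.53. Genes of mesenchymal transition had a median of 0.24 over 7 members at percentile 99.4, with ITGA5 at 0.64 and VIM at 0.58. Histone genes had a median of 0.12 at percentile 99.2, with H4C8 at 0.65 and H2BC21 at -0.40. Housekeeping genes, chosen as a control list, had a median of 0.09 at percentile 97.6, with POLR2A at 0.24. In all, 3 of the 25 lists lay below and 8 above the middle 95% of random lists, where 1.25 would lie outside by chance if genes varied independently.

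Genes of the LSD1 complexes, a list that counts the targeted gene KDM1A itself, had a median of -0.08 at percentile 8.17. Only KDM1A passed 1.5-fold in that list. Its paralog KDM1B was at -0.55 and HDAC1 at 0.49. The protein kinase C family had a median of 0.09 at percentile 95.5, with PKN2 at -0.28 and PKN3 at 0.24. Androgen metabolism genes had a median of -0.02 at percentile 33.3. Among them the retinol dehydrogenase gene RDH11 was at -0.79, UGT2B11 and UGT2B28 were both at -0.62, and AKR1C2 was at 0.64. Neuronal targets of the REST repressor had a median of 0.01 at percentile 52.9, with NEFL at -0.30 and TUBB3 at 0.15. Targets of p53 had a median of 0.04 at percentile 91.2, with TP53INP1 at -0.64 and BBC3 at 0.46. Genes of endoplasmic reticulum stress had a median of -0.04 at percentile 32.7, with DDIT3 at 0.46 and ATF3 at 0.43.

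Of the cell type marker lists, luminal epithelial genes had a median of 0.02 over 17 members at percentile 72.7, with KRT19 at 0.75 and ELF3 at 0.57. Only 4 of 13 basal epithelial genes reached 1 FPKM, and their median was 0.59, above all random lists. SFN was at 1.17 and 2.65 FPKM and LAMB3 at 3.18 and 5.90 FPKM. The neuroendocrine list had 3 measured genes with a median of 0.18 (percentile 85.6), led by ENO2 at 0.36 and SYT11 at 0.18. The fibroblast and smooth muscle list had 3 with a median of 0.36 (percentile 99.5), led by COL1A1 at 0.38 and ACTA2 at 0.36. The immune list had 4 with a median of 0.04 (percentile 56.1), led by CD68 at 0.52 and HLA-DRA at -0.17. The endothelial list had 1, VWF at 0.23 (percentile 80.5).

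**Figure D2:**
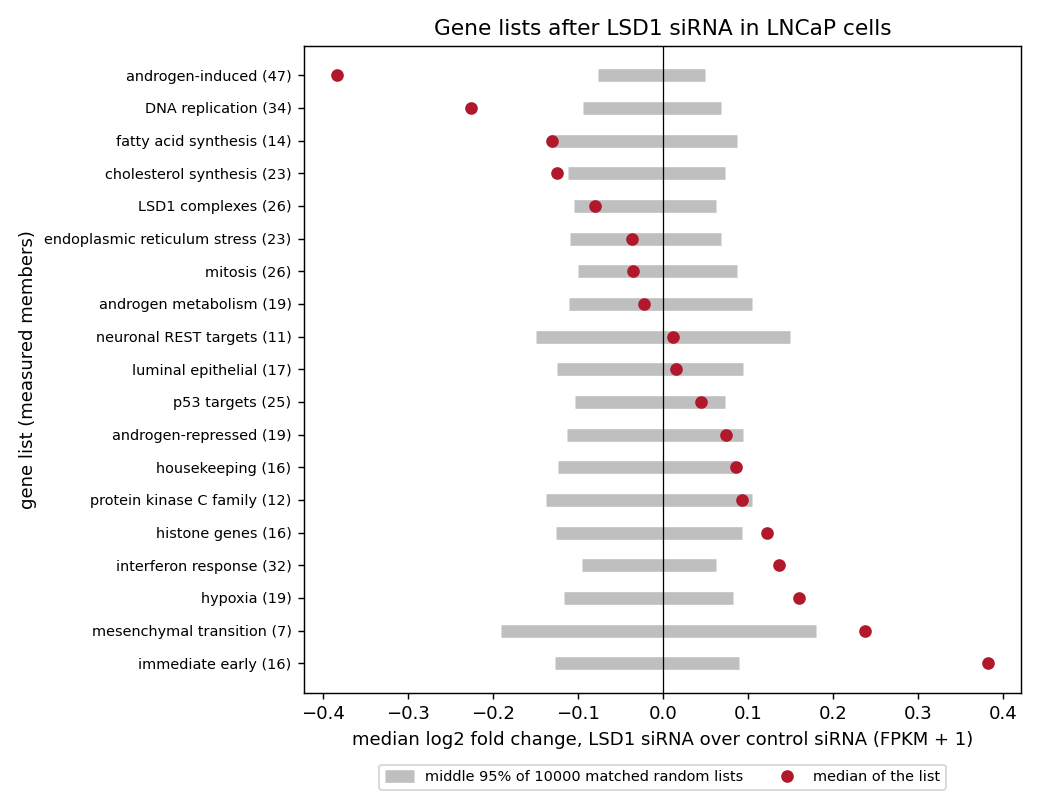
Points give the median log2 fold change of gene lists with at least 6 measured members, LSD1 siRNA over control siRNA in LNCaP (1 library each, FPKM + 1 scale), and grey bars the middle 95% of 10000 random lists matched on expression. Androgen-induced genes (-0.38) and DNA replication genes (-0.23) lie left of their bars and immediate early genes (0.38) lie right.

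The peak lists were then compared. Median peak width was 730 bases for LSD1 in LNCaP, 850 for LSD1 in VCaP and 466 for H3T6ph in LNCaP. Peaks covered 9.04, 9.88 and 2.30 Mb in the same order. Gene intervals held 52.2% of LNCaP LSD1 peaks, with a 95% Wilson interval of 51.3 to 53.1%, against a mean of 41.1% over 100 random placements. A peak within 1 kb of an end of a gene interval was more frequent for VCaP LSD1, at 17.6% (16.9 to 18.4%), than for LNCaP LSD1, at 9.59% (9.07 to 10.1%), or H3T6ph, at 6.91% (6.2 to 7.69%). Random placements of the 3 lists gave mean values of 3.90, 3.37 and 3.17% in that order.

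LSD1 occupied mostly different called sites in the LNCaP and VCaP samples, with a shared part far above chance. Of LNCaP LSD1 peaks 1218 of 11673 overlapped a VCaP LSD1 peak, which is 10.4% (9.89 to 11%), against 0.420 to 0.788% over random placements. Of VCaP LSD1 peaks 1214 of 9854 overlapped an LNCaP LSD1 peak, which is 12.3% (11.7 to 13.0%), against 0.487 to 0.893%. The share was higher among peaks with a high score from the authors. It was 16.8% (15.5 to 18.2%) among the 2918 highest-scoring LNCaP peaks and 7.33% (6.44 to 8.33%) among the 2919 lowest-scoring. A called list leaves out sites below its threshold, so a site in 1 list alone may still be bound in the other line.

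Within LNCaP, H3T6ph and LSD1 peaks met at 676 of the 4460 H3T6ph peaks. This was 15.2% (14.1 to 16.2%) of the H3T6ph list, against 0.314 to 0.830% over random placements. Seen from LSD1, 678 of 11673 peaks, or 5.81% (5.40 to 6.25%), overlapped H3T6ph, against 0.0942 to 0.326%. More H3T6ph peaks of LNCaP overlapped LSD1 peaks of VCaP, 1154 of 4460 or 25.9% (24.6 to 27.2%), against 0.291 to 0.874%. This share was 48.6% (45.7 to 51.5%) among the 1115 highest-scoring H3T6ph peaks and 12.4% (10.6 to 14.4%) among the 1115 lowest-scoring. For LNCaP LSD1 the shares of the same peaks were 24.3 and 10.1%. All 3 lists met at 336 H3T6ph peaks, 7.53% (6.80 to 8.35%) of that list. With overlaps of at least 50% of each peak the shares of H3T6ph peaks were 11.1% for LNCaP LSD1 and 13.4% for VCaP LSD1. With the top 4460 peaks of each list they were 8.52 and 18.4%, and without peaks present in all 3 lists 8.22 and 19.6%.

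**Figure D3:**
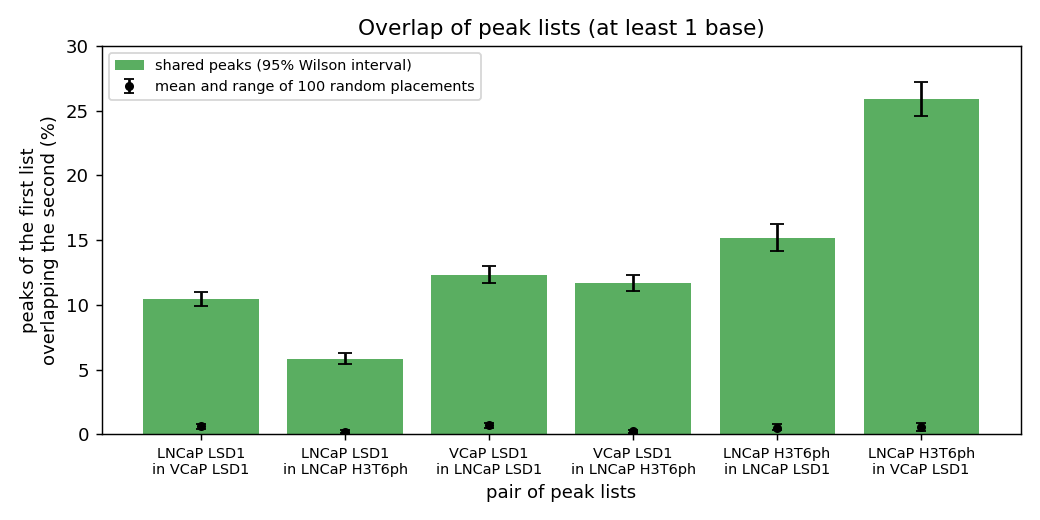
Bars give the percentage of the first list's peaks that overlap the second list by at least 1 base, with 95% Wilson intervals, and points the mean and range over 100 random placements of the second list. The share of LNCaP H3T6ph peaks in the VCaP LSD1 list (25.9%) is the highest of the 6, and all random values lie below 1%.

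The highest-scoring peaks recurred across antibodies. The top peak of VCaP LSD1 lay on chromosome 1 at 91852634 to 91853291, within the HFM1 interval, with a score of 2977. The same place held the top H3T6ph peak (91852677 to 91853251, score 1731) and the second LNCaP LSD1 peak (91852632 to 91853299, score 895). The top LNCaP LSD1 peak, on chromosome 6 at 58776073 to 58779459 with a score of 1347, lay 488 kb from the nearest gene interval. It overlapped both other lists and was met by the third VCaP LSD1 peak, at 58773286 to 58780166 (score 1037). The third LNCaP LSD1 peak lay on chromosome 7 at 61968622 to 61970032 (score 862), 782 kb from a gene interval, and also overlapped both other lists. The second VCaP LSD1 peak, on chromosome 18 at 106685 to 110378 within ROCK1P1 (score 1326), overlapped LNCaP LSD1. The second H3T6ph peak, on chromosome X at 77359201 to 77359934 at PGK1 (score 846), overlapped no other list. The third, on chromosome 12 at 20704252 to 20704613 within PDE3A (score 828), overlapped both.

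Near KLK3 (chromosome 19, 51358171 to 51364020) all 3 lists held a peak. These were at 51353751 to 51354592 for LNCaP LSD1 (score 58.5), 51353697 to 51354477 for H3T6ph (score 81.0) and 51353180 to 51355973 for VCaP LSD1 (score 81.6). They lay 3.58, 3.69 and 2.20 kb from the low-coordinate end of the gene, the side on which its androgen-responsive enhancer is known to lie. Close to KLK2 (51376689 to 51383823), LNCaP LSD1 had a peak at 51372494 to 51373518 (score 126), and another at 51392570 to 51393385 that met an H3T6ph peak at 51392591 to 51393531. No VCaP LSD1 peak lay within 20 kb of KLK2, and the nearest was just past that limit, at 20.7 kb. FKBP5 held peaks of all 3 lists inside its interval, among them an H3T6ph peak at 35690106 to 35690849 on chromosome 6 (score 272). None of the lists had a peak within 20 kb of TMPRSS2, though an H3T6ph peak lay just past that limit, at 20.3 kb. At KDM1A itself VCaP LSD1 had a peak at the low-coordinate end (23345337 to 23346062), H3T6ph had one 1.19 kb past the other end, and the nearest LNCaP LSD1 peak was 260.5 kb away.

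**Figure D4:**
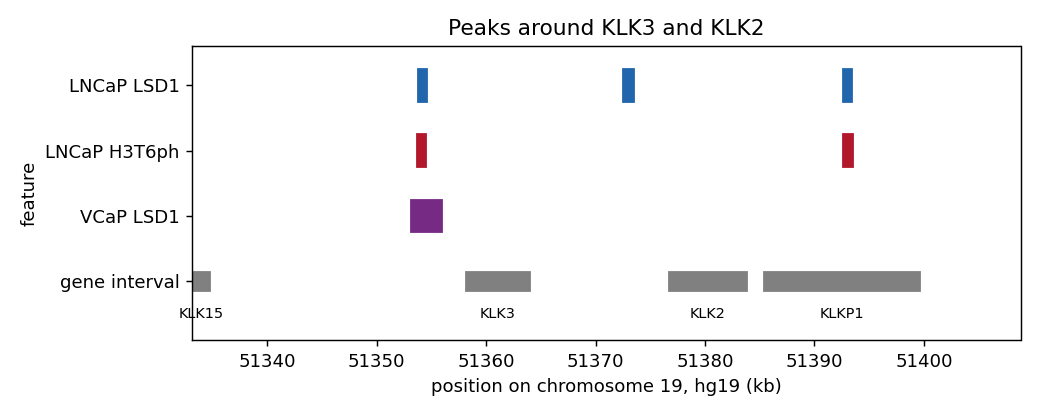
Boxes mark peaks of the 3 lists (rows) and gene intervals (bottom row) on chromosome 19 from 51333171 to 51408823 (hg19, axis in kb). All 3 lists have a peak on the low-coordinate side of KLK3, and LNCaP LSD1 and H3T6ph meet again within KLKP1.

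The last comparison joined binding and expression in LNCaP. The share of called genes near an LSD1 peak lay within the range of random genes of like expression. Of 108 higher genes with an interval, 39 (36.1%, 27.7 to 45.5%) had an LNCaP LSD1 peak within 20 kb, at percentile 13.2 of matched sets. Of 145 lower genes, 52 (35.9%, 28.5 to 43.9%) had one, at percentile 9.65. Both sets consisted mostly of short RNA genes. Some of these share an interval, as SNORD44 and SNORD75 do among the lower genes, and so count the same peaks. The intervals and percentiles for called genes do not allow for this. For H3T6ph the shares were 18.5% of higher genes (percentile 59.3) and 22.8% of lower genes (percentile 94.1). With length matched as well, the sets gave a mean of 16.6% for the lower genes, whose share then lay at percentile 97.8. For a site shared by LSD1 and H3T6ph they were 4.63% (percentile 73.6) and 3.45% (percentile 50.7), and for VCaP LSD1 38.9% (percentile 31.7) and 38.6% (percentile 25.2). The 5319 genes near an LNCaP LSD1 peak had a median log2 fold change of -0.01, at percentile 66.2. The 2305 near an H3T6ph peak also had a median of -0.01, at percentile 50.3. Genes near a VCaP LSD1 peak had a median of -0.01 too, but at percentile 99.9. For the 510 genes near an H3T6ph site in the VCaP and not the LNCaP LSD1 list the median was 0.01, at percentile 98.9 (99.7 with length matched), and the 472 protein-coding genes among them lay at percentile 94.4 (97.9). For the 442 genes near a site shared by LSD1 and H3T6ph in LNCaP it was -0.03, at percentile 3.45 (9.27 with length matched), and the 409 protein-coding genes among them had a median of -0.04 at percentile 0.570 (1.98). These medians are all far within 1.5-fold, and 10 such medians were computed. Among protein-coding genes called at 2-fold, a set defined after the data were seen, 10 of 15 lower genes (66.7%, 41.7 to 84.8%) and 7 of 13 higher genes (53.8%, 29.1 to 76.8%) had an LSD1 peak nearby, against 42.6% of all protein-coding genes. Both intervals include that share. Against sets matched on expression and length the lower genes lay at percentile 98.0 and the higher genes at 89.8. With the higher-scoring 50% of LSD1 peaks the shares of all called genes were 17.6% of higher and 21.4% of lower genes.

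Androgen-induced genes lay near H3T6ph peaks, and near sites shared by LSD1 and H3T6ph, more often than matched genes. This set of comparisons was chosen after the data were seen. Of the 47 genes, 28 (59.6%, 45.3 to 72.4%) had an LNCaP LSD1 peak within 20 kb, against 41.3% in matched sets (percentile 99.3). With interval length matched as well, the sets gave 47.2% (percentile 96.6). H3T6ph peaks lay near 17 (36.2%, 24.0 to 50.5%), against 21.5% with length matched (percentile 99.1). A site shared by both marks lay near 10 (21.3%, 12 to 34.9%), against 5.27% with length matched (percentile 100). These included NNMT, SLC45A3, KLK2, C1orf116, KLK3, ALDH1A3, KLK4, IGF1R and ZBTB16, of which the 3 kallikrein genes are neighbours that can share a peak. Luminal epithelial genes, whose median did not stand apart from random lists, also lay near H3T6ph peaks more often than matched genes, in 9 of 17 (52.9%, 31.0 to 73.8%), at percentile 99.98 with length matched. KRT8 and KRT18 on that list have the same interval and so count the same peaks. Over all lists and peak sets 125 such shares were computed. Of these, 10 lay outside the middle 95% with length matched, where chance would give 6.25.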

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

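Alternatives to the protein-coding and accession choices, the removal of peaks present in all 3 lists, random lists from all genes and all settings for H3T6ph in VCaP LSD1 were chosen after seeing the data. No paired analysis was possible because each group has 1 sample. Of 83 alternative values 39 stayed within the limits set for them (1.5 times for counts, the 95% interval for shares and medians, 0.1 for KDM1A), and 44 moved. Counts and shares cannot change sign. None of the values for KDM1A, the 2 androgen lists and the medians near peaks did. No alternative varied the depth. By the estimate from low values, a 2 kb transcript at the 1 FPKM filter rests on about 59.3 and 45.8 fragments, which limits the precision of values near it. The androgen-induced median ran from -0.41 to -0.36, below all random lists in each of its 5 alternatives, and the androgen-repressed median from 0.05 to 0.09, at percentiles 90.7 to 95.6. KDM1A moved to -2.41 with a pseudocount of 0.1 FPKM.

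The counts of higher and lower genes were 247 and 311 at 1.5-fold, as a lower threshold must give more, 13 and 15 for protein-coding genes and 14 and 17 for genes of 300 bases or more. Counted as accessions, they were 532 and 623 by the 2-fold rule and 63 and 79 by the calls in the authors' deposited table. The share of higher genes among those called stayed between 42.7 and 46.8%.

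For overlaps the values are given in the order LNCaP LSD1 in VCaP LSD1, the reverse, H3T6ph in LNCaP LSD1, the reverse, and H3T6ph in VCaP LSD1. With an overlap of at least 50% of each peak they were 7.38, 8.74, 11.1, 4.22 and 13.4%. Within 1 kb they were 11.5, 13.6, 16.2, 6.26 and 26.6%. With the higher-scoring 50% of each list they were 9.03, 10.6, 13.7, 5.24 and 29.8%. With every list reduced to its top 4460 peaks they were 9.57, 9.51, 8.52, 8.54 and 18.4%. Without peaks present in all 3 lists they were 7.66, 9.14, 8.22, 2.99 and 19.6%. These changes follow from which peaks and overlaps each setting admits. H3T6ph met VCaP LSD1 more often than LNCaP LSD1 in each of the 5.

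The shares of higher and lower genes with an LNCaP LSD1 peak were 24.1 and 24.1% at 5 kb, 50 and 53.8% at 50 kb, and 17.6 and 21.4% with the higher-scoring 50% of peaks. For protein-coding genes they were 53.8 and 66.7%, and for protein-coding genes at 1.5-fold 38.0 (percentile 14.8) and 48.5% (percentile 92.3). Percentiles ran from 2.25, for lower genes at 5 FPKM or more, to 96.7. Length matching gave 49.9 and 23.4. The median of genes near an LNCaP LSD1 peak was -0.020 with a filter of 5 FPKM, and that near an H3T6ph peak within 50 kb reached percentile 99.9 at a median of -0.0027. The cause of these changes was not tested.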

Other observations

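The tests of short RNAs, of the scaling and of members near LSD1 peaks, and the gene families and shared-site genes, were chosen only after the results were seen. The tests of why H3T6ph met VCaP LSD1 were set down before their results were seen. Of 17 gene families, picked after their values were seen, 12 had a median outside the middle 95% of matched random lists, which is no independent evidence. None of the family members named here passed the 2-fold rule, and the authors' deposited table called only RLN1 and LCN2 among them. Relaxin genes RLN1 (36.9 and 19.3 FPKM) and RLN2 (17.2 and 8.68 FPKM) had log2 fold changes of -0.90 and -0.91. All 4 measured metallothionein genes, which bind metals, were above 0 with a median of 0.61, led by MT1G at 24.9 and 48.0 FPKM. The secreted inhibitor and lipocalin genes PI3, SLPI and LCN2 were at 0.95, 0.85 and 0.77. Of 8 keratin genes 6 were above 0, with a median of 0.58. Among them KRT80 (0.727 and 2.27 FPKM) was at 0.92, KRT20 (2.36 and 5.19 FPKM) at 0.88 and KRT19 (2.39 and 4.70 FPKM) at 0.75. The far more abundant KRT8 (929 and 718 FPKM) and KRT18 (620 and 461 FPKM) were lower, at -0.37 and -0.43. Mitochondrial ribosomal protein genes had a median of -0.09, with 60 of 77 below 0, while cytosolic ribosomal protein genes had a median of -0.00 over 74. Centring, which adds 0.02 to each value, changes none of these directions except that of the last median.

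Sites shared by LSD1 and H3T6ph in LNCaP also lay near protein-coding genes that were at least 1.5-fold lower after LSD1 siRNA. Of 136 such genes 14 (10.3%, 6.23 to 16.5%) had a shared site within 20 kb, against 3.37% in sets matched on expression and length. Protein-coding genes at least 1.5-fold higher had one in 5 of 121 (4.13%, percentile 86.1 with length matched). At 2-fold the order was the other way, with 2 of 13 higher genes (percentile 98.0) and 1 of 15 lower genes (percentile 74.5). H3T6ph sites in the VCaP and not the LNCaP LSD1 list also lay near protein-coding genes at least 1.5-fold lower, in 11 of 136 (8.09%, percentile 98.3). Over genes of all types at least 1.5-fold lower they did not stand apart, with 14 of 305 (4.59%, percentile 83.9 with length matched). Without members of the androgen-induced list the share of lower genes near a site shared in LNCaP was 11 of 124 (8.87%, 5.03 to 15.2%), against 3.11%. Of the 40 shares computed for called genes, 7 lay outside the middle 95% of sets matched on expression and length, where chance would give 2. The genes included OTULINL (18.7 and 8.82 FPKM), MYBPC1 (log2 -0.88), SPOCK1 (-0.81), GOLM1 (-0.64), GMDS (-0.63), MBOAT2 (-0.63) and ATAD2 (-0.59). Genes at least 1.5-fold higher with such a site included CXCL8 (0.66), C19orf33 (0.91), CLU (1.32) and MAN1A1 (1.35). The only H3T6ph peak near MAN1A1 (chromosome 6, 119558186 to 119558904, score 443) also overlapped a VCaP LSD1 peak with a score of 973. A pile-up of reads that does not depend on the antibody cannot be excluded there. The shares near shared sites were not recomputed without peaks present in all 3 lists.

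Of the accessions called in the authors' deposited table, 78 had sister accessions of the same gene at 1 FPKM or more. In 71 of them the summed sisters moved the opposite way, and 71 belonged to genes whose sum stayed within 1.5-fold. Peak names in each list are numbered, and 3, 8 and 6 numbers are absent from the LNCaP LSD1, VCaP LSD1 and H3T6ph lists; those peaks were not analysed here.

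Androgen-induced genes were lower after LSD1 siRNA. A shift of all genes by the scaling of the libraries is argued against by the list's percentile of 0 among matched random lists. A larger fall in genes near LSD1 peaks was not resolved: 28 members with a peak had a median of -0.40 and 19 without had -0.36, a difference at percentile 24.8 of random divisions of the list. A change in other regulators of these genes, which the design does not separate from lower LSD1, stays open. Whether the response to androgen or the basal level of the list was lower cannot be told, as hormone treatment did not differ. Off-target effects of the siRNA and chance differences between 2 cultures also stay open, since the design has 1 library for each and 11 of 25 lists stood apart from random lists.

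Most genes past the 2-fold rule were short RNAs, 55.7% of all short genes against 0.248% of longer ones. Single reads on transcripts shorter than the sequenced fragments are a candidate explanation. Of the 224 called short RNAs, 67.0% (60.6 to 72.8%) were listed at 0 in 1 library. Any gene at 0 in 1 library and at 1 FPKM or more in the other passes the 2-fold rule by definition. This share among called genes therefore cannot decide about single reads. The lower depth of the LSD1 siRNA library is consistent with the direction, as 59.3% (51.3 to 66.9%) of those seen in 1 library were at 0 after LSD1 siRNA, where the depth ratio gives 56.4%. An effect of LSD1 on particular short RNAs was not tested, and these values cannot settle it. With 204 bases taken off each length by the depth estimate, genes under 300 bases keep little or no length. Of called short RNAs above 0, 45 of 163 in the control library shared a value with another. In the LSD1 siRNA library it was 44 of 135.

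H3T6ph peaks of LNCaP met LSD1 peaks of VCaP more often than those of LNCaP. Wider or more peaks are argued against as the whole explanation: with 9854 peaks from each LSD1 list and 200 bases per peak, the shares were 19.3% (18.1 to 20.4%) and 11.7% (10.8 to 12.7%). Shared regions wider than such a move are argued against as the source of the overlap, because 3.35% of it was kept after moving VCaP peaks by 50 to 500 kb. The same move of LNCaP LSD1 peaks kept 4.27% of their overlap with H3T6ph. It therefore does not address why the VCaP share was higher, and narrower shared regions were not tested. Pile-ups that do not depend on the antibody may account for the top peaks found in all 3 lists. Sites shared by H3T6ph and VCaP LSD1 alone lay near androgen-induced genes (6 of 47) at percentile 99.4, or 98.1 with length matched. They also lay near luminal epithelial genes, in 5 of 17 at percentile 99.98 with length matched. The test assumed that pile-ups do not favour such genes, which was not examined, so it cannot decide. The overlap with VCaP LSD1 reached 72% among the top 100 H3T6ph peaks by score. Pile-ups therefore stay open. A difference in sensitivity between the ChIP samples and a difference between the cell lines both stay open, and neither was tested.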
